A study of Homo sapiens with 6 samples.

How the data were processed

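The 6 arrays comprised 3 control and 3 cisplatin samples of HuH7 cells. Per the labels, total RNA was labelled with Hy5 by a commercial miRNA labelling kit. The scanner files hold linear intensity values, per the file headers the median and mean of the pixels of each spot and of its local background. All 3200 spots of each array had flag 0. The series text speaks of 1719 human probes, while the files hold 2019, of which 15 carry several names. The scanner and its software are not given in the sources used here.

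The authors' processed table, deposited with the series, holds intensity on a linear scale with a median of 31 on every array. Set against the scanner values, it equals the foreground median minus the mean of the blank spots, with 5% trimmed at each end, divided by 1 factor per array. The largest residual was 5.8e-06. Probes at or below the trimmed mean plus 2 SD are not listed in it, 1031 to 1321 of 2019 per array. It was used only as an alternative, and the direction is that of the arrays themselves.

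Foreground and local background medians were corrected with normexp (offset 50), quantile-normalized over the human probes and put on the log2 scale, in limma 3.58.1 under R 4.3.3. Figures were drawn with matplotlib 3.10.9. The offset and the quantile step shrink the folds of dim probes. A bright probe that held 1 rank on all arrays of a group gets identical values there, as miR-19b-3p, miR-20b-5p and miR-122-5p did in control and miR-130a-3p in cisplatin arrays, and its SE is then too small. A probe was detected where its foreground lay above the mean plus 2 SD of the 925 blank spots of its array. The limits were 220, 239.83 and 228 for control and 209, 247 and 227 for cisplatin arrays. A few bright blanks widened the SD of cisplatin replicate 2 to 18.0, so fewer probes counted as detected there. Tested were the 324 probes detected on all 3 arrays of at least 1 group, and 243 were detected on all 6.

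Groups were compared with lmFit and eBayes (4 residual and 1.52 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. A probe below the limit on every array of 1 group has a bound only, the mean of the brighter group over the mean of, per array, the higher of the lowest detected signal and its own. Of 22 lists fixed in advance, 15 had at least 3 tested probes and were tested with camera (preset correlation 0.01), with fry and an estimated correlation beside it. With the estimated correlation 0 lists were called, and fry, which does not compare a list with other probes, called 4, but 0 when any array other than control replicate 1 was left out and 3 with the replicate block. Fry's further lists were the liver-enriched miRNAs (adjusted p = 0.0445) and those studied in cisplatin response (adjusted p = 0.0258). Counts and median signal per array were compared with an exact two-sided permutation test.

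The groups, the tests, the lists and most alternative settings were fixed before the data were examined. Text names follow a rule fixed then too. It takes the probes past the threshold, filled to 10 in each direction by the smallest unadjusted p, up to 4 probes of each list by mean signal, and the 5 brightest probes. This gave 78 miRNAs, and miR-34a-5p and miR-34b-5p were added after their values were seen. The text describes each list with some of these, and the closing part covers all 80.

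Samples of the same number deviated together from their group means, with correlations over the tested probes of 0.44, 0.24 and 0.20 for numbers 1, 2 and 3. All exceed 0.1, so the numbers were taken to pair the samples. Cisplatin 2 and control 3 correlated too (0.23), so the check does not single out the numbers for replicates 2 and 3. The pairing comes from the labels' numbers and this check, not from a stated design. The fit with the replicate number as a block is given beside the results it changes.

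Arrays lay at slide positions 3, 1 and 3 (control 1, 2 and 3) and 4, 2 and 4 (cisplatin 1, 2 and 3). No position held both groups, so position and group cannot be told apart. Positions 1 and 2 held replicate 2 of each group, and positions 3 and 4 the others. Within these, the median of the miR-23/24/27 list was 0.38 between the arrays at positions 1 and 2, and 0.55 in the fit of the arrays at positions 3 and 4. For the miR-17 to miR-92 list the values were -0.30 and -0.19. With this division as a block, 1 probe passed and both lists held (adjusted p = 2.8e-05 and 2.6e-06). With position as a random block, 47 probes passed, but the estimated correlation within positions was negative (-0.62), which shrinks the standard errors, so that count is not relied on.

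The steps were tested on data simulated for the real probes, with 20 simulations per size over the 324 tested probes, and the outcome was mixed. With no change, 0.0154% of probes were called over all simulations together, and 5.39% had an unadjusted p under 0.05. A call thus also arose where nothing had been changed. With 40 probes changed by 0.5, 1 or 2 on the log2 scale, 49.9%, 91.4% and 98.5% were recovered, at a median of 0.86, 0.83 and 0.81 of the true change. The share of false calls was 9.32%, 12.2% and 34.9%, above the nominal 5%. On the same simulated values it was 4.85%, 5.37% and 5.37% with cyclic loess, and 4.0%, 4.55% and 5.78% with median scaling, so in these simulations the excess came with the quantile normalization. Apart from background, the simulated arrays differed by 1 factor each, which median scaling removes. They do not cover differences between arrays that change with intensity, so they cannot rank the normalizations for the real arrays. Quantile normalization was kept because it was fixed in advance, and the calls under those alternatives stand beside its own. A list raised by 0.5 was called in 20, 20 and 13 of 20 simulations with the preset correlation and in 0 with an estimated one. The test with an estimated correlation thus missed every simulated list, while the simulated probes vary independently, so the simulations do not cover correlated probes.

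Alternatives covered background correction, normalization, the authors' values, the detection filter, blocks, moderation, thresholds and leaving out each array. Chosen after seeing the data were a detection limit from trimmed blank spots, scaling to the 16 spots named Spike Control, positions 3 and 4 alone, pixel means and leaving out probes of fixed rank. Taking the median of repeated spots did not apply, since each probe has 1 spot. No genome build is named by the files, so no coordinates are given. A RefSeq gene table of assembly GRCh38.p14 served only to tell which hairpins are neighbours, and 311 of 324 probes matched a locus in it.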

Results

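MicroRNA levels were measured in HuH7, an established human hepatocellular carcinoma cell line, with and without cisplatin, a platinum drug that crosslinks DNA. Cells received 1 µg/ml cisplatin or none for 24 h, and total RNA from 3 control and 3 cisplatin samples was hybridised to 1-colour arrays. Each array carried 2019 human miRNA probes with 1 spot each and 925 blank spots. The labels number the samples of each group from 1 to 3, and nothing in them says that these were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

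Control arrays had 703, 500 and 738 probes above the blank-spot limit, and cisplatin arrays 713, 329 and 643. The means were 647 ± 128.5 and 562 ± 205 detected probes (SD, n = 3 each), a difference that the exact two-sided permutation test did not separate (p = 0.6, where 0.1 is the smallest p possible). Median raw foreground signal of the human probes was 221.3 ± 6.66 in control and 216 ± 12.3 in cisplatin arrays (SD, n = 3 each, exact permutation p = 0.6). Within same-numbered pairs the median raw signal was lower in the cisplatin array in 3 of 3, as was that of the blank spots, but the exact sign-flip p cannot lie below 0.25 with 3 pairs.

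The main comparison asked which miRNAs differ after cisplatin, the question named by the series. In the main analysis no tested probe reached a 2-fold difference. miR-1304-3p (MIMAT0022720) was the 1 probe of 324 that passed, and it rose, with a log2 fold change of 0.59 (SE 0.049, limma adjusted p = 0.0118). It was above the blank limit on 3 of 3 cisplatin arrays and on 0 of 3 control arrays. Its difference is thus given as at least 1.30-fold, a bound on the scale of the main analysis only. The fitted log2 value depends on background correction, from 0.22 without it to 1.06 with plain subtraction. Its raw foreground reached at most 251 after cisplatin and 220 in control arrays, without overlap between the groups and close to the background in both. With the replicate number as a block, 0 probes passed (smallest adjusted p = 0.161, 57 probes at an unadjusted p under 0.05). In fits that left out 1 array miR-1304-3p passed only without cisplatin replicate 2 (adjusted p = 0.0391). Cyclic loess and median scaling each passed 4 probes, miR-23b-3p, miR-23a-3p and miR-191-5p in both, with miR-1304-3p under the former and miR-27a-3p under the latter. Both normalizations made fewer false calls on simulated data, whose arrays differed by 1 factor each, a difference that median scaling removes.

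At an unadjusted p under 0.05 there were 51 probes, 26 higher and 25 lower after cisplatin, where chance alone would give 16.2. Leaving out the 5 probes that held the same rank on every array gave 40 of 319, where chance would give 15.95. In that fit miR-1304-3p passed with a limma adjusted p of 0.0277. The probes with the smallest p after miR-1304-3p did not pass, and their values follow. On the higher side were miR-425-5p (log2 fold change 0.39, SE 0.064) and miR-191-5p (0.47, SE 0.11), which come from neighbouring hairpins. miR-27a-3p had the largest value of all tested probes at 0.60 (SE 0.14), followed on this side by miR-23a-3p (0.55), miR-23b-3p (0.51), miR-130a-3p (0.35, but 0.13 with cyclic loess), miR-27b-3p (0.26) and miR-30b-5p (0.24). miR-4484 stood at 0.40, but at -0.04 when pixel means replaced pixel medians. On the lower side were miR-19b-3p (-0.40, SE 0.054, adjusted p = 0.0706, but -0.24 with median scaling) and miR-20b-5p (-0.27, SE 0.041, adjusted p = 0.0909, but -0.12 with median scaling). Both arms of miR-122, the most abundant miRNA of liver, were also there, miR-122-3p at -0.37 and miR-122-5p at -0.21. The others were miR-18b-5p (-0.32), miR-4737 (-0.32, given as at least 1.24-fold lower since 0 of 3 cisplatin arrays were above the blank limit), miR-17-3p (-0.28), miR-320a (-0.25, but -0.15 with median scaling), miR-3648 (-0.24, but -0.11 with median scaling) and miR-140-3p (-0.22). The bound for miR-4737 also holds on the scale of the main analysis only, and its log2 value ranged from -0.90 to -0.12 over the other settings.

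**Figure D1:**
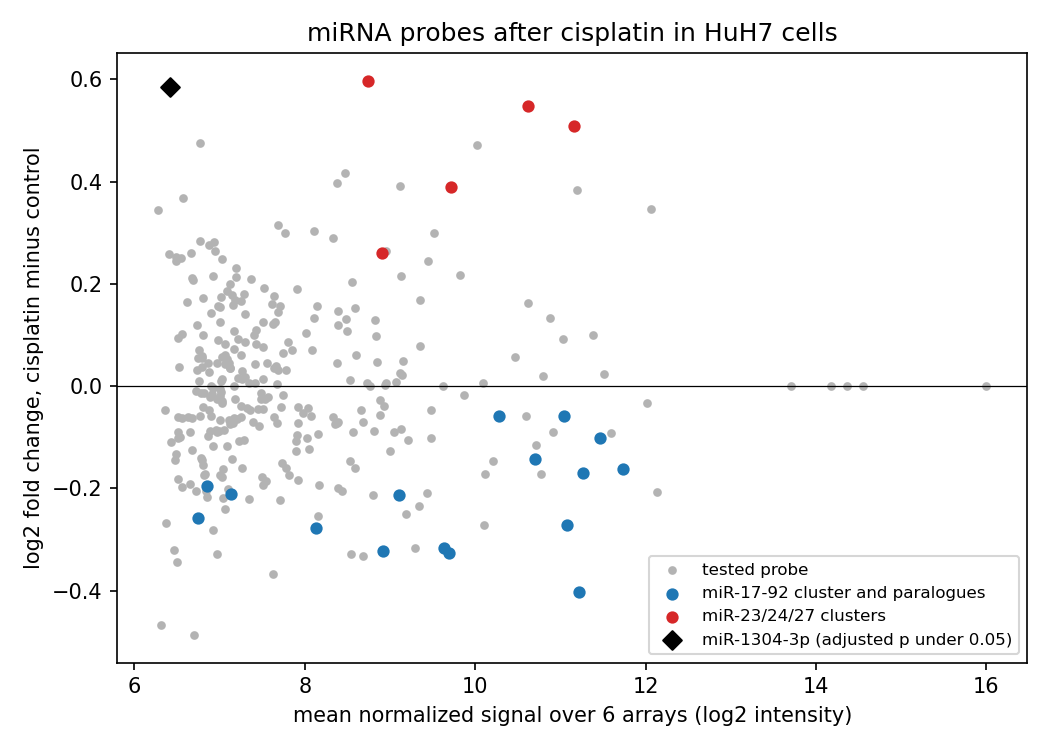
Log2 fold change (cisplatin minus control, vertical axis) against mean normalized log2 intensity over 6 arrays (horizontal axis) for the 324 tested probes, 1 point each. The miR-23/24/27 probes (red) lie above 0 and the miR-17 to miR-92 probes (blue) below it, while miR-1304-3p (black) passed at the dim end of the range.

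Of 15 miRNA lists with enough tested probes, the miR-23/24/27 clusters rose after cisplatin. All 5 tested probes of this list were positive, with a median log2 fold change of 0.51, and all 5 were higher in the cisplatin array of each of the 3 same-numbered pairs. Over all 11 probes of the list on the array, without the detection filter, the median was 0.21. miR-23b-3p, miR-23a-3p, miR-24-3p (0.39, SE 0.11) and miR-27b-3p were the brightest tested members. Camera gave the list an adjusted p of 3.1e-05, but the call was lost with an estimated correlation (adjusted p = 0.234). Adjusted over the list alone, 5 of 5 probes passed, against 0 of 5 over all probes tested.

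The miR-17 to miR-92 cluster and its paralogues, a group known for promoting proliferation, fell. All 16 tested probes were negative, with a median log2 fold change of -0.21 and a range from -0.40 to -0.057 (camera adjusted p = 1.1e-06, but the call was lost with an estimated correlation, adjusted p = 0.225). When arrays were scaled to the 75th percentile the median was -0.042 (adjusted p = 0.0457), or -0.15 less the shift of all tested probes by 0.11 under that scaling. The brightest members were miR-17-5p (-0.16, SE 0.18), miR-106a-5p (-0.10, SE 0.096), miR-20a-5p (-0.17, SE 0.16) and miR-19b-3p. Of these, miR-106a-5p stood at 0.011 and miR-20a-5p at 0.058 with the 75th percentile, but at -0.096 and -0.049 less that shift. Adjusted over the list alone, 4 of 16 probes passed, miR-19b-3p, miR-20b-5p, miR-18b-5p and miR-17-3p (8 with the replicate block), against 0 over all probes tested. The call was also lost without normalization between arrays (median -0.066, adjusted p = 0.0623).

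**Figure D2:**
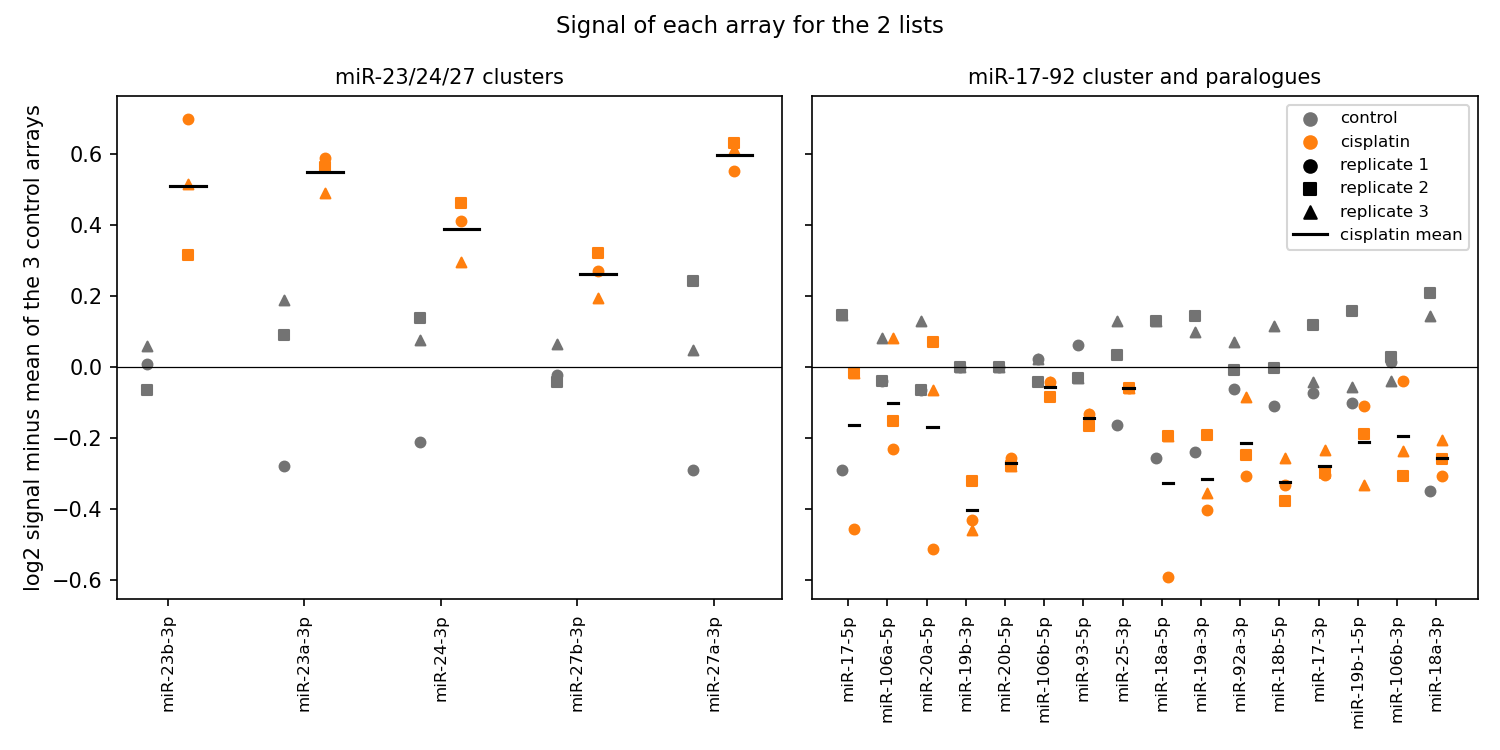
Log2 signal of each array minus the mean of the 3 control arrays (vertical axis) for each probe of the lists that passed, with control arrays in grey, cisplatin arrays in orange, marker shape for the replicate number and a bar for the cisplatin mean. Cisplatin arrays lie above control arrays for the 5 miR-23/24/27 probes, while for the 16 miR-17 to miR-92 probes the groups overlap in several members, such as miR-17-5p and miR-20a-5p.

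The other 13 lists did not pass camera in the main analysis. Liver-enriched miRNAs had 6 of 8 probes negative and a median of -0.13 (adjusted p = 0.0633), which became 0.026 with the 75th percentile, or -0.081 less the shift. Over all 15 probes of the list on the array, without the detection filter, the median was -0.0011. This list was called with detection on all 6 arrays (adjusted p = 0.0110), without control replicate 1 (0.0282), without cisplatin replicate 3 (0.0330) and with pixel means (0.0270), while the median shrank to -0.074 without cisplatin replicate 1 and to -0.073 without control replicate 2. Their brightest members after miR-122-5p were miR-194-5p (0.021, SE 0.090) and miR-192-5p (-0.058, SE 0.069), the latter at 0.39 with the 75th percentile, or 0.28 less the shift. Adjusted over the list alone, 2 of these 8 passed, both arms of miR-122, and 0 with the replicate block. The p53-associated miRNAs had 8 of 10 probes positive and a median of 0.077 (adjusted p = 0.355), and the list was called with median scaling (0.19, adjusted p = 0.0486) and with the authors' values (adjusted p = 0.0110), while the median was 0.026 without control replicate 1. Their brightest probes were miR-107 (0.093, SE 0.076) and miR-16-5p (0.13, SE 0.099). miR-34a-5p and miR-34b-5p, both direct targets of p53 and named here after their values were seen, lay on opposite sides at 0.31 (SE 0.083, adjusted p = 0.146) and -0.28 (SE 0.079, adjusted p = 0.167), and neither passed. Of the 10, 0 passed adjusted over the list alone.

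Among miRNAs studied in cisplatin response, 4 probes were positive and 4 negative, with a median of 0.12 (adjusted p = 0.204) that became -0.015 when arrays were scaled to spike spots, or 0.085 less the shift of all tested probes by -0.10. The median was 0.30 for probes detected on all 6 arrays, 0.0155 without a detection filter and 0.027 with cyclic loess. Adjusted over the list alone, 4 of 8 passed (3 with the replicate block), all higher in the main fit, among them miR-130a-3p and miR-21-5p (0.38, SE 0.094). The miRNAs raised in hepatocellular carcinoma had a median of 0.038 (adjusted p = 0.343), with miR-21-5p and miR-221-3p (0.22, SE 0.056) as the brightest of 12. When 1 array was left out this median ranged from -0.0029 to 0.12. The 5 probes of the miR-15/16 family were all positive, with a median of 0.13 (adjusted p = 0.137) and miR-15b-5p at 0.22 (SE 0.14), and the list was called with median scaling (0.34, adjusted p = 0.0377), scaling to spike spots (adjusted p = 0.0183) and pixel means (adjusted p = 0.0371). Its median ranged from 0.080 to 0.22 when 1 array was left out. The 3 probes of the miR-29 family were positive too, with a median of 0.21 (adjusted p = 0.204) and miR-29a-3p at 0.30 (SE 0.16), both 0.14 without control replicate 1, and the median was 0.59 with the authors' values, or 0.44 less the shift. Adjusted over the list alone, 0 probes passed in these 3 lists, and 1 of the miR-15/16 family with the replicate block.

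Most of the remaining lists lay near 0. Medians were 0.013 for the let-7 family (adjusted p = 0.93), 0.017 for the miR-99/100 and miR-125 families (0.608), -2.3e-05 for the miR-30 family (0.741) and 4.3e-04 for the mirtrons (0.741). The GC-rich and RNA-fragment-like probes had a median of -0.018 (adjusted p = 0.84) and the chromosome 19 cluster -0.047 (adjusted p = 0.741). Endothelial, stromal and muscle markers, which HuH7 cells are not expected to supply, had 4 of 15 probes tested and a median of 0.093 (adjusted p = 0.585), which ranged from 0.0034 to 0.16 when 1 array was left out and was 0.50 with the authors' values, or 0.35 less the shift. Each of these medians except those of the chromosome 19 cluster and of the endothelial, stromal and muscle markers changed sign, less the shift, under at least 1 other normalization. Adjusted over the list alone, 1 GC-rich probe passed, miR-4484, and none did in the others of these lists, with 1 mirtron passing with the replicate block.

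Another 7 lists had too few tested probes. The miR-200 family, miR-183 cluster, miR-26 family and 14q32 cluster had 2 each, with medians of 0.13, 0.17, 0.16 and -0.17, and 1 of them, miR-182-5p, passed adjusted over the list alone, but not with the replicate block. The neural markers had 1, miR-128 (-0.058, SE 0.12). The miR-371 to miR-373 cluster and the blood cell markers had 0 of 7 and 0 of 11 probes tested.

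**Figure D3:**
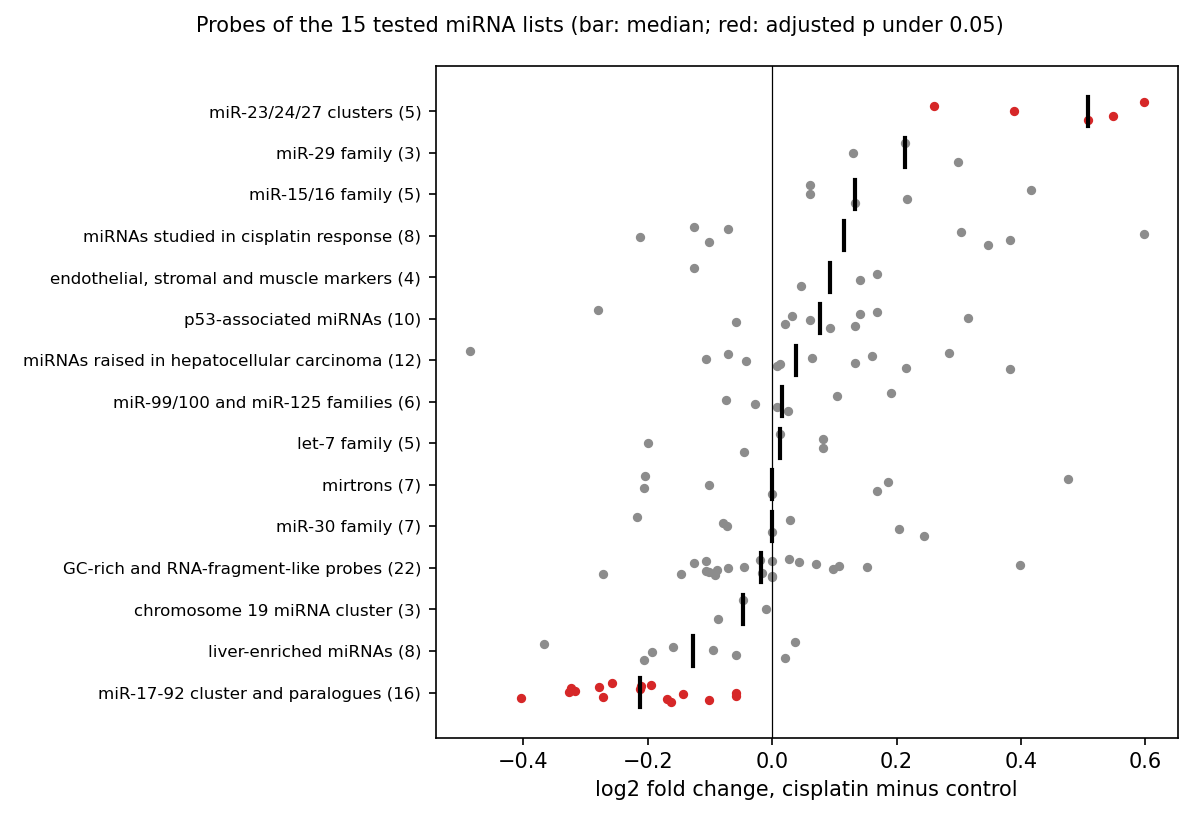
Log2 fold change (cisplatin minus control, horizontal axis) of each tested probe, 1 row per list with its number of tested probes, a bar at the median, and red points where the camera adjusted p was under 0.05. The medians run from -0.21 for the miR-17 to miR-92 list to 0.51 for the miR-23/24/27 list.

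The brightest probes were miR-4454, miR-1260b, miR-5100, miR-4286 and miR-4284. miR-4454 was saturated on all 6 arrays. Raw foreground ranged from 19163 to 27899 for miR-1260b, from 18962 to 23779 for miR-5100, from 15893 to 20480 for miR-4286 and from 8847 to 17014 for miR-4284. These 5 held the same rank on every array, so quantile normalization gave them identical values in both groups and no fold is reported.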

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

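Chosen after seeing the data were the trimmed blank limit, Spike Control scaling, positions 3 and 4 alone, pixel means and leaving out probes of fixed rank. The median of all tested probes shifted by 0.15 with the authors' values, 0.11 with the 75th percentile, 0.083 without normalization and -0.10 with Spike Control scaling. Less that shift, 5 of 15, 7 of 15, 7 of 13 and 2 of 12 of the sign turns given below for these settings remain, and the others reflect the common shift. Except where stated, the cause of a change was not tested.

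The number of probes that passed was 1 with quantile normalization. It was 3 without background correction (1 higher, 2 lower), 3 with the 75th percentile, 4 with median scaling and 4 with cyclic loess (all higher in these 3), and 5 at an adjusted p under 0.10. Without probes of fixed rank it was 1, at both thresholds. The number was 0 without normalization, with the authors' values, without a detection filter (2019 probes tested, smallest limma adjusted p = 0.728) and for probes detected on all 6 arrays. It was also 0 with the replicate block, with trend and robust moderation, with Spike Control scaling, at positions 3 and 4 only (fewer arrays) and with pixel means. At an unadjusted p under 0.05 the limma fits with 0 had 33, 29, 97, 39, 57, 38, 13, 38 and 34 probes, where chance would give 15.9 with the authors' values, 101 without a filter, 12.2 for detection on all 6 arrays and 16.2 in the others, so no excess was left without a filter or with Spike Control scaling. With slide position as a random block 47 passed. Leaving out arrays gave 0 to 3, with 3 without cisplatin replicate 2 and 0 without any of the other 5. miR-1304-3p is not listed in the authors' values on enough arrays to be fitted.

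The number of lists called was 2, and 4 with median scaling (also the p53-associated miRNAs and the miR-15/16 family), 4 with pixel means (also the miR-15/16 family and the liver-enriched miRNAs), 4 with fry (also the liver-enriched miRNAs and those studied in cisplatin response), 1 without normalization and 0 with an estimated correlation. It was 3 with the authors' values (also the p53-associated miRNAs), with Spike Control scaling (also the miR-15/16 family), and with detection on all 6 arrays, without control replicate 1 and without cisplatin replicate 3 (also the liver-enriched miRNAs). Fry's count was 0 when 1 of the 5 arrays other than control replicate 1 was left out, and 0 with median scaling, the 75th percentile, Spike Control scaling, the authors' values, no normalization and positions 3 and 4 alone. It was 1 with cyclic loess, without a filter and with the division of the positions as a block, 2 without background correction, and 3 with the replicate block and without probes of fixed rank. The miR-23/24/27 median kept its sign under all 25 alternatives (0.21 to 0.79) and its call under all but the estimated correlation (0.51 there, adjusted p = 0.234). The miR-17 to miR-92 median was negative under all 25 (-0.28 to -0.042), and the call was lost with the estimated correlation (-0.21, adjusted p = 0.225) and without normalization (-0.066, adjusted p = 0.0623). Some of the 25 could not move these medians. They were the replicate block, the division of the positions as a block, the estimated correlation, fry and leaving out probes of fixed rank. For those settings the kept sign says nothing. The replicate block changed no list call by camera, and no call over all probes but that of miR-1304-3p. Of the 80 named miRNAs, 75 had a direction and 45 kept it throughout, among them 18 of the 20 with the smallest p. Those 2 blocks, moderation and the detection filter could not change the value of a single miRNA. The 45 leaves out miRNAs that turned only within the common shift, such as miR-106a-5p and miR-3648. Less the shift, 5 of these 20 were over 1.5 times smaller than in the main analysis under at least 1 other normalization (miR-130a-3p at 0.14, miR-19b-3p at -0.24, miR-20b-5p at -0.12, miR-320a at -0.15 and miR-3648 at -0.10), 2 were over 1.5 times larger (miR-27b-3p at 0.42 and miR-4737 at -1.06) and 0 turned.

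The sign turned, with these log2 values, as follows. With the 75th percentile it turned for the liver-enriched miRNAs (0.026), the miR-30 family (0.13), the GC-rich probes (0.12), miR-3648 (0.0037), miR-192-5p (0.39), let-7e-5p (0.087), miR-106a-5p (0.011), miR-20a-5p (0.058), miR-30c-5p (0.21), miR-30e-5p (0.055), miR-100-5p (0.19), miR-125a-3p (0.11), miR-128 (0.031), miR-4516 (0.18) and miR-1228-5p (0.068). Without normalization it turned for the liver-enriched miRNAs (0.0011), the miR-30 family (0.10), the GC-rich probes (0.093), miR-192-5p (0.36), let-7e-5p (0.063), miR-20a-5p (0.033), miR-30c-5p (0.18), miR-30e-5p (0.030), miR-100-5p (0.16), miR-125a-3p (0.087), miR-128 (0.0067), miR-4516 (0.16) and miR-1228-5p (0.044). The authors' values turned the miR-30 family (0.28), the GC-rich probes (0.13), miR-192-5p (0.36), let-7e-5p (0.14), miR-20a-5p (0.0073), miR-30c-5p (0.22), miR-30e-5p (0.067), miR-100-5p (0.16), miR-125a-3p (0.098), miR-517c-3p (0.056), miR-518d-3p (0.014), miR-214-3p (0.43), miR-128 (0.014), miR-4516 (0.14) and miR-1228-5p (0.037). Median scaling turned the let-7 family (-0.024), the miR-30 family (0.015), the GC-rich probes (0.0065), miR-192-5p (0.28), let-7d-5p (-0.0020), miR-30c-5p (0.095), miR-100-5p (0.076) and miR-4516 (0.069). Cyclic loess turned the miR-30 family (3.3e-05), the miR-99/100 and miR-125 families (-0.031), the mirtrons (-0.082), miR-192-5p (0.12), miR-151a-5p (-0.035), miR-30c-5p (3.3e-05), miR-99a-5p (-0.034), miR-125b-5p (-0.030), miR-494 (-0.054) and miR-1234-5p (-0.093). Spike Control scaling turned the let-7 family (-0.12), the miRNAs studied in cisplatin response (-0.015), the endothelial, stromal and muscle markers (-0.0075), the mirtrons (-0.039), miR-192-5p (0.18), let-7a-5p (-0.027), let-7d-5p (-0.097), miR-200a-3p (-0.025), miR-125b-5p (-0.0047), miR-494 (-0.031), miR-126-3p (-0.017) and miR-1234-5p (-0.039). Without background correction the sign turned for the miR-30 family (0.0072), the chromosome 19 miRNA cluster (0.0084), let-7e-5p (0.0095), miR-30c-5p (0.0072), miR-517c-3p (0.0084), miR-518d-3p (0.010) and miR-494 (-0.015). Plain subtraction turned the miR-30 family (0.00016) and miR-30c-5p (0.00016), and offset 16 the miR-30 family (3.6e-05) and miR-30c-5p (3.6e-05). Without a detection filter it turned for the let-7 family (-0.034), the miR-30 family (0.040), the endothelial, stromal and muscle markers (-0.066) and the mirtrons (-0.017), with detection on all 6 arrays for the miR-30 family (0.015), and with the trimmed limit for the let-7 family (-0.016), the miR-30 family (0.015) and the mirtrons (-0.017). Position as a random block turned miR-30c-5p (0.011), miR-125b-5p (-0.028), miR-125a-3p (0.0090), miR-517c-3p (0.0030) and miR-128 (0.0014). Positions 3 and 4 alone turned the let-7 family (-0.064), miR-30c-5p (0.013), miR-125b-5p (-0.060), miR-125a-3p (0.081), miR-517c-3p (0.016) and miR-128 (0.056). Pixel means turned miR-4484 (-0.042), miR-194-5p (-0.0085), let-7e-5p (0.020), miR-100-5p (0.067), miR-517c-3p (0.068) and miR-494 (-0.018).

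Leaving out 1 array at a time also turned signs, with these ranges. Among lists they were the let-7 family (-0.043 to 0.066), the miRNAs raised in hepatocellular carcinoma (-0.0029 to 0.12), the miR-30 family (-0.077 to 0.069), the miR-99/100 and miR-125 families (-0.026 to 0.085), the chromosome 19 miRNA cluster (-0.093 to 0.020), the GC-rich probes (-0.046 to 0.028) and the mirtrons (-0.051 to 0.085). Among miRNAs they were miR-194-5p (-0.033 to 0.090), miR-192-5p (-0.087 to 0.0065), let-7e-5p (-0.12 to 0.057), let-7d-5p (-0.00086 to 0.16), miR-20a-5p (-0.29 to 0.0034), miR-15a-5p (-0.029 to 0.15), miR-151a-5p (-0.11 to 0.11), miR-210 (-0.031 to 0.082) and miR-96-5p (-0.0080 to 0.082). Further ranges were miR-30c-5p (-0.077 to 0.069), miR-30e-5p (-0.19 to 0.029), miR-26a-5p (-0.010 to 0.12), miR-99a-5p (-0.085 to 0.11), miR-125b-5p (-0.063 to 0.056), miR-100-5p (-0.087 to 0.064), miR-125a-3p (-0.14 to 0.045), miR-517c-3p (-0.050 to 0.020) and miR-518d-3p (-0.18 to 0.081). The last were miR-494 (-0.035 to 0.037), miR-126-3p (-0.084 to 0.17), miR-128 (-0.18 to 0.017), miR-4516 (-0.28 to 0.052), miR-1234-5p (-0.10 to 0.085) and miR-1228-5p (-0.22 to 0.031). None of these lists or miRNAs had passed. Lists that kept their sign ranged over 0.41 to 0.54 (miR-23/24/27), -0.28 to -0.19 (miR-17 to miR-92), 0.026 to 0.12 (p53-associated), 0.080 to 0.22 (miR-15/16), -0.14 to -0.073 (liver-enriched), 0.099 to 0.16 (studied in cisplatin response), 0.14 to 0.28 (miR-29) and 0.0034 to 0.16 (endothelial, stromal and muscle markers).

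The difference in detected probes (cisplatin minus control) ranged from -161 to 31 when 1 array was left out, positive without cisplatin replicate 2. That in median raw signal ranged from -10.83 to 1.17, positive without cisplatin replicate 1, and was 4.67 after subtraction of the local background. Signal over background limits all of this, since at most 738 of the 2019 probes lay above the blank limit on any array.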

Other observations

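The tests on slide position, on the spread of miR-1304-3p, on sequence families, on neighbouring hairpins and on arms were chosen after the values were seen, at least in part. Besides the human probes, the arrays carry 31 kinds of spot named S-Probe, whose identity is not given in the sources used here. Of these, 12 were detected on all 6 arrays, and 0 of the 12 had every cisplatin array above every control array after normalization, where 0.6 would be expected by chance. Before normalization, the spots named Spike Control were brighter in the cisplatin array of each pair, by 0.19, 0.087 and 0.27 on the log2 scale. After normalization the group means (cisplatin minus control) differed by -0.0996 for Spike Control 1 and -0.016 for Spike Control 2.

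The miR-17 to miR-92 list lay lower and the miR-23/24/27 list higher after cisplatin. Sharing of label between near-identical sequences is argued against as the whole cause for the miR-23/24/27 list. There the miR-23, miR-24 and miR-27 families rose by 5.51, 3.28 and 5.22 SE. In the miR-17 to miR-92 list 3 of 4 families fell by more than 2 SE, with miR-18 at 2.29 SE (exact permutation p = 0.2), while miR-25 and miR-92 stopped at 1.94 SE. Its families were grouped by name and join arms of unlike sequence, such as miR-17-5p and miR-17-3p, so they are no clean test of label sharing. A trend with brightness is argued against too, since the medians lay at percentiles 0 and 100 of 10000 random lists matched on signal. The position of the array on the slide cannot be told apart from treatment, because 0 positions held both groups. The 10 splits of the arrays are too few for a share under 0.05: the real split called 2 lists and the highest other 2, and of the 3 others that also part all 3 same-numbered pairs 1 called lists, the let-7 family and miR-23/24/27, while miR-17 to miR-92 was called in 2 others that part 1 pair each, so a response to cisplatin stays a hypothesis.

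miR-1304-3p was the 1 probe past the threshold. Its SD within groups, 0.038, lay at percentile 4 among the 100 tested probes nearest in signal, whose median SD was 0.145, so a spread that is small by chance may account for the call. The splits are again too few for a share under 0.05, with 1 probe in the real split, 0 in the highest other and 1 split reaching the real count. Among the 4 splits that part all 3 same-numbered pairs, the real one had 51 probes at an unadjusted p under 0.05 and the others 4 to 10, while a split that parts 1 pair had 36. A change at a signal near background stays open.

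Hairpins that are neighbours within 10 kb were compared with each other. Outside the lists that passed, 23 pairs of neighbours of unlike sequence differed in log2 fold change by 0.104 on average, against 0.179 for permuted hairpins (one-sided permutation p = 0.00246, adjusted over 4 such tests 0.00328). With hairpins permuted among those of like signal, in 3 signal strata, p was 0.00323. This argues against brightness as the whole cause only at that coarse grain, since signal still varies within a stratum. Neither permutation holds the size of the changes of the paired hairpins fixed. A small difference may thus also mean that both members of a pair changed little. Only 14 of 23 pairs shared a sign, so a shared direction is not shown and a joint response of neighbours stays a hypothesis. miR-191 and miR-425 (0.47 and 0.26) and miR-193b and miR-365a (0.18 and 0.20) were pairs on the higher side. The last pair is outside the naming rule. Its miR-193b rise rests on replicate 1, with log2 signals of 7.24 in control and 7.76 in cisplatin. They were 7.69 and 7.71 in replicate 2, and 7.70 and 7.70 in replicate 3. The value for miR-425 is the mean of its 5p arm (0.39) and its 3p arm (0.13).

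The 5p and 3p arms of 23 hairpins outside those lists differed by 0.137 on average, against 0.18 for permuted arms (one-sided permutation p = 0.0163), with 13 of 23 sharing a sign. Here too the size of the changes was not held fixed, so both arms may simply have changed little. No permutation among arms of like signal was run. A shared direction of the arms is thus not shown. With the lists included p was 0.00182 over 27 hairpins. The hairpins added there, miR-17, miR-18a, miR-19b and miR-106b, belong to the miR-17 to miR-92 list. That list was called in these same data because its probes lay lower, so the smaller p is no further evidence.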
